A study of Mus musculus with 6 samples.

How the data were processed

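Poly(A)-selected RNA was sequenced from RN2 cells, a mouse acute myeloid leukaemia line that carries MLL-AF9 and NrasG12D. Per the labels, the cells expressed doxycycline-inducible short hairpin RNAs and were harvested after 48 hours of doxycycline. Libraries were made from total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. The labels name 6 libraries: 2 with a Renilla luciferase control hairpin (shRen), 2 with a hairpin against Med12 (named shMed12.401 and shMed12.5755) and 2 with a hairpin against Med23 (named shMed23.678 and shMed23.4061). Groups were taken from the sample titles. The 2 hairpins of a target were the replicates of its group, and nothing in the labels says whether libraries came from separate cultures on separate days, so p-values measure the spread between these libraries, which may be partly technical.

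The submitters' processing notes name TopHat, Cufflinks and Cuffdiff and the mouse build mm9, with versions not given in the sources used here. The authors' deposited table holds FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for each of the 4 knockdown libraries, per the file headers. Beside each stands the authors' log2 fold change against the Renilla control, per the file headers. The deposited table gives no separate value for either shRen library. A control FPKM was computed for each gene from a library's FPKM and its log2 fold change, and the values from the 4 libraries differed by a relative 1.3e-05 at most. It is called the authors' control value here. How the authors made it from their shRen libraries is not given in the sources used here, and it has no SD or n.

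The table lists 8380 genes, of which 8359 have a value in all 4 libraries. The control value of listed genes is 5.0015 FPKM or more, and 0 genes lie at 5 or below, so genes that were off or low in control cells and rose after knockdown are outside the data. In 74 genes, all with a small RNA symbol, at least 1 library is listed at 0, and these were left out of the main test, which leaves 8285 genes. Of these, 864 share their listed locus with another gene, so that reads could be divided between them, and 378 have a Mir, Snor, Rnu, Gm or Rik symbol. As deposited, 15 gene symbols had been turned into calendar dates, and all 15 were resolved from their locus with a RefSeq gene table. FPKM values carry no read counts, so the depth of each library is unknown and no counting interval or detection floor can be given. The FPKM of listed genes summed to 557775 for shMed12.401, 540236 for shMed12.5755, 557979 for shMed23.678, 549465 for shMed23.4061 and 562738 for the control value. Strand use in counting is not given in the sources used here, so overlapping and antisense genes cannot be separated. Coordinates are mm9 as the table gives them.

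Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), over genes with a mean FPKM of at least 1, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at adjusted p under 0.05. All fold changes from this fit are on the log2(FPKM + 1) scale, which understates changes of low genes. The design written before the data were examined assumed 6 libraries in 3 groups. Since the table gives 1 control value, the fit held 4 knockdown libraries and 1 control value, and the control value was assumed to vary like a single knockdown library. That leaves 2 residual degrees of freedom, both from the difference between the hairpins of a target, to which the trend added 4.18 prior degrees of freedom. Comparisons with shRen and the difference between shMed12 and shMed23 were contrasts of this 1 fit.

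Before the data were examined, 29 gene lists were fixed, and 21 with at least 5 tested genes were tested with limma camera at a preset correlation between genes of 0.01, adjusted over lists. Camera with an estimated correlation and fry were run beside it. The estimate rests on 2 residual degrees of freedom, and with it 0 lists passed in any comparison. Fry, adjusted over lists, passed 6 lists in shMed12 against shRen (cytosolic ribosomal proteins, macrophage, antigen presentation, interferon-stimulated, ATF4 and lysosome genes; lowest adjusted p = 0.0483). It passed 0 in shMed23 against shRen (lowest 0.0531) and 0 between the knockdowns (lowest 0.384). Of the other 8 lists, 3 had 0 tested genes (erythroid, B and T lymphocyte, and fibroblast and stromal markers). Coverage was uneven, and list results hold for tested genes alone. All 42 MYC targets were tested, but 24 of 42 macrophage, 15 of 24 neutrophil granule, 11 of 32 interferon-stimulated and 9 of 23 antigen presentation genes. Named genes were chosen by a rule written before the data were examined. In each comparison with shRen it took the targeted gene, the 10 called genes with the largest rise and the 10 with the largest fall whose 2 knockdown libraries lay on the same side of the control value, with a symbol that occurs once. It added up to 2 called genes with the largest rise and 2 with the largest fall from each list, and 10 fixed genes (Med12, Med23, Myc, Hoxa9, Meis1, Myb, Cdk6, Bcl2, Itgam and Brd4). Between shMed12 and shMed23 it took up to 5 called genes each way, and for the overlap the 5 genes called in both in each direction with the largest smaller change. Symbols that only name an RNA class were left out of these lists; 27 of the calls for shMed12 and 4 of those for shMed23 have such a symbol. The rule as written asked for both shRen libraries, in whose place the control value was used.

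Both comparisons share the control value, so 100 sets of unchanged groups were simulated against 1 shared control value with the fitted spread. For the overlap of calls, lists of the observed sizes were taken from each set by rank of p, a test added after the data were seen. The fit was tested on simulated data of 8285 genes, of which 67 were changed by 0.5 (log2), 67 by 1 and 66 by 1.5. For shMed12 against shRen it called 53.7%, 100% and 100% of these. For shMed23 against shRen it called 49.3%, 98.5% and 100%. In the same runs 13 and 14 unchanged genes were called. With no changed genes it called 1 gene and 3 genes. These runs drew each gene independently, with the fitted spread and a control value that varied as the fit assumes. They test the fit under its own assumptions, so recovery in the real data may be lower. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter (genes listed at 0 included), a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, a fit of the compared groups alone, eBayes without the trend, robust eBayes, limma treat at a fold of 1.2, and leaving out each knockdown library in turn. Alternatives chosen after the data were seen were a control value weighted as 2 libraries, leaving out genes of a shared locus, leaving out Mir, Snor, Rnu, Gm and Rik symbols, and a correction of each library for transcript length (loess, span 0.5, lengths from GENCODE transcripts for 99.5% of tested genes). Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib.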

Results

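RNA levels were measured in RN2 mouse leukaemia cells after doxycycline-induced knockdown of Med12 or Med23, which are subunits of Mediator, the complex that links transcription factors to RNA polymerase II. Med12 belongs to the kinase module of Mediator and Med23 to its tail. The design had 2 control libraries (shRen), 2 shMed12 libraries and 2 shMed23 libraries, each knockdown library with a different hairpin. Values are given as FPKM for the 4 knockdown libraries and as 1 authors' control value, with the depth of each library unknown. The comparisons ask which genes responded to loss of each subunit, in a study whose title concerns release of Mediator under BET inhibition.

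Each targeted gene was lowest in the libraries labelled with its own hairpins. Med12 (mm9 chromosome X, 98469429 to 98494273) was at 7.31 and 7.32 FPKM in the shMed12 libraries, against a control value of 14.3 and 13.5 and 13.9 FPKM in the shMed23 libraries. The shMed12 mean, 7.32 ± 0.012 (SD, n = 2), was 51.3% of the control value. Med23 (chromosome 10, 24589791 to 24633335) was at 3.23 and 3.48 FPKM in the shMed23 libraries, against a control value of 9.74 and 8.31 and 8.86 FPKM in the shMed12 libraries. The shMed23 mean, 3.35 ± 0.178 (SD, n = 2), was 34.4% of the control value. In the authors' deposited table the log2 fold change of Med12 was -0.96 for both hairpins shMed12.401 and shMed12.5755, and that of Med23 was -1.59 for shMed23.678 and -1.49 for shMed23.4061. Both falls passed the limma test in the comparison with shRen (Med12 log2 fold change -0.88, SE 0.10, adjusted p = 0.0198; Med23 -1.30, SE 0.11, adjusted p = 0.0373). Leaving out either shMed23 library ended both calls, with Med12 at -0.88 and Med23 between -1.35 and -1.26. None of the 24 tested genes of the head, middle and tail of Mediator and none of the 5 tested genes of the kinase module other than Med12 was called in either comparison, and 0 passed when adjusted over the list alone. These lists contain neither targeted gene.

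**Figure D1:**
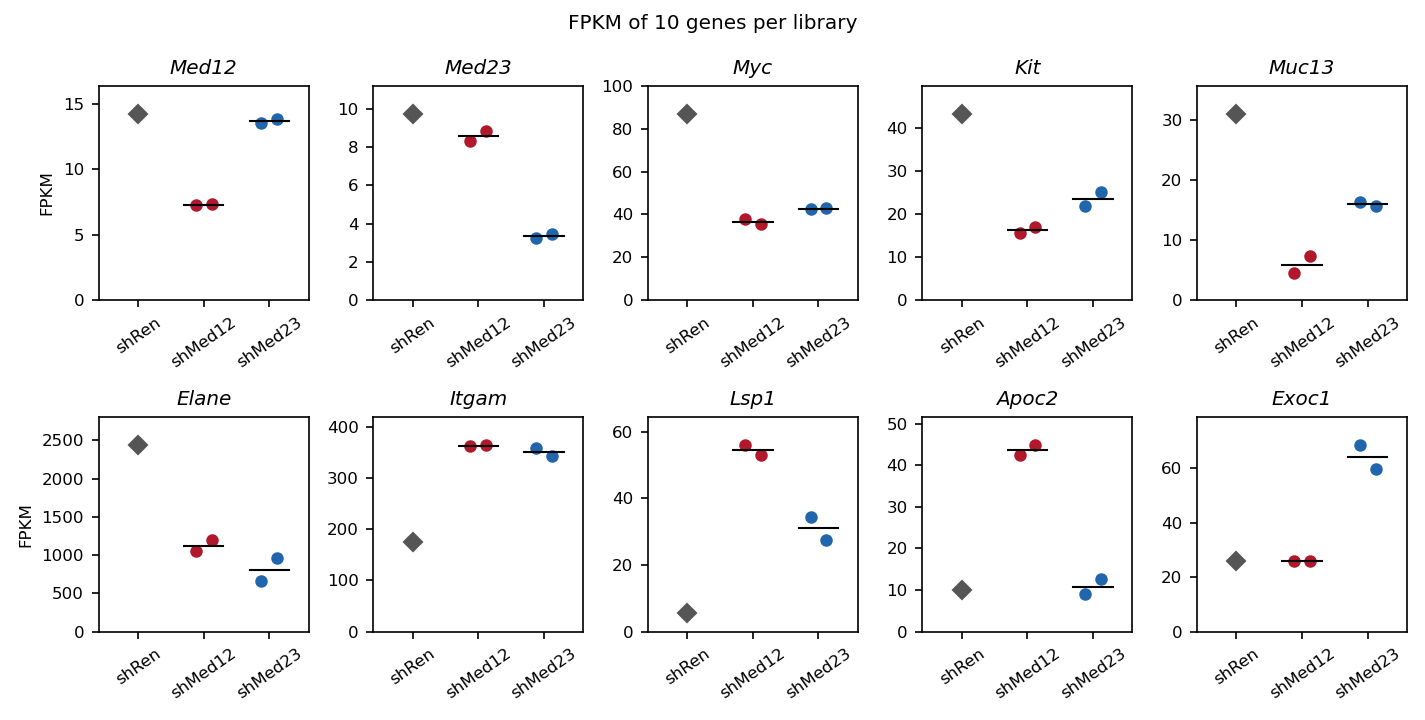
FPKM of 10 genes in each library, on linear axes that start at 0; the diamond is the authors' control value, points are single knockdown libraries and black lines are means of 2 libraries. Med12 was lowest in the shMed12 libraries (7.31 and 7.32 FPKM) and Med23 in the shMed23 libraries (3.23 and 3.48 FPKM), while Apoc2 was high in the shMed12 libraries alone and Exoc1 in the shMed23 libraries alone.

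After Med12 knockdown Myc and Kit fell and Lsp1 and Itgam rose. Myc, a transcription factor that drives growth, went from a control value of 87.0 FPKM to 36.7 ± 1.81 (SD, n = 2), and Kit, the receptor for stem cell factor, from 43.2 to 16.3 ± 0.911. Lsp1, an actin-binding protein of leukocytes, showed the largest rise, from 5.54 to 54.4 ± 2.09 FPKM. Itgam, which encodes the CD11b chain of a myeloid integrin, rose from 176 to 363 ± 0.331 FPKM. In total 484 of 8285 genes were called, of which 206 rose and 278 fell.

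Among called genes, Mir, Snor, Rnu, Gm and Rik symbols aside, the 10 largest rises after Med12 knockdown were in Lsp1 (log2 fold change 3.08, SE 0.14, adjusted p = 0.00429), Apoc2 (2.02), Itgb7 (2.01), Slfn2 (1.93), Lgals3 (1.85), Cyp4f18 (1.62), Xdh (1.60), Lilrb4 (1.52), Wfdc17 (1.51) and Il18rap (from 5.21 to 16.6 ± 2.27 FPKM). Several of these encode proteins of myeloid or other immune cells, such as galectin-3 (Lgals3), the integrin beta 7 chain (Itgb7), an inhibitory receptor of the immunoglobulin family (Lilrb4) and an accessory chain of the interleukin-18 receptor (Il18rap). Apoc2, an apolipoprotein that activates lipoprotein lipase, went from 9.99 to 43.7 ± 1.60 FPKM. The 10 largest falls among them were in Muc13 (-2.24, SE 0.23, adjusted p = 0.0185), Rangrf (-1.37), Kit (-1.36), Ass1 (-1.31), Fam195a (-1.24), Myc (-1.22), Chchd10 (from 11.3 to 4.43 ± 1.22 FPKM), Fpgs (-1.17), Stc2 (-1.16) and Srm (-1.15). Muc13, a cell surface mucin, was at 5.92 ± 2.01 FPKM, 19.1% of the control value. Srm encodes spermidine synthase and Fpgs an enzyme of folate metabolism. Fpgs shares its listed locus with another gene, so its value is uncertain.

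The list of MYC targets in the nucleolus and ribosome biogenesis had the lowest camera adjusted p of the lists in shMed12 cells but did not pass fry (adjusted p = 0.0879). This list also holds MYC targets of other functions, such as Srm, Bzw2 and Ldha. Of its 42 tested genes 28 fell, 0 rose and 14 were not called, and 39 fell when adjusted over the list alone. The median log2 fold change was -0.71 (camera adjusted p = 9.08e-20; adjusted p = 0.417 with an estimated correlation). Srm went from 103 to 45.7 ± 3.26 FPKM and Bzw2 from 43.1 to 20.8 ± 0.669 FPKM (log2 fold change -1.02). The 28 tested cytosolic ribosomal proteins had a median of -0.21 with 0 called, and 0 when adjusted over the list alone (camera adjusted p = 2.99e-04; adjusted p = 0.417 with an estimated correlation), and were not called as a list with quantile normalization. In the list of ATF4 and unfolded protein response genes 7 of 24 fell and 0 rose, and 14 fell when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 1.09e-06; adjusted p = 0.318 with an estimated correlation). Its largest called falls were in Phgdh, the first enzyme of serine synthesis (-1.14), and the transcription factor Atf5 (-0.87), which shares its listed locus with another gene. Among heat shock genes the mitochondrial chaperonins Hspd1 (-0.82) and Hspe1 (-0.70) fell, 10 of 12 were not called, and 5 fell when adjusted over the list alone (median -0.28, camera adjusted p = 0.00897; adjusted p = 0.417 with an estimated correlation).

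Genes known to be sensitive to BET inhibitors in leukaemia were lower on balance. Of 14 tested genes 5 fell (Kit, Myc, Gfi1, Erg and Etv6), 0 rose and 9 were not called, and 7 fell when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.0193; adjusted p = 0.417 with an estimated correlation). Without shMed12.5755 this list was not called, at a median of -0.24. Gfi1, Erg and Etv6 were named here after their values were seen, to complete the count. Myb (log2 fold change -0.51, SE 0.14, adjusted p = 0.0861), Cdk6 (-0.66, SE 0.19, adjusted p = 0.0905), Bcl2, which shares its listed locus with another gene (-0.15, SE 0.11, adjusted p = 0.441), and Brd4 (0.03, SE 0.12, adjusted p = 0.913) were not called. In the list of MLL-AF9 and HOXA9 target genes 0 of 13 were called, and 0 when adjusted over the list alone, while the list lay slightly higher (median 0.16, camera adjusted p = 0.0311; adjusted p = 0.417 with an estimated correlation) and was not called without shMed12.401, at 0.10, with quantile normalization or without genes of a shared locus. Hoxa9 (0.16, adjusted p = 0.640) and Meis1 (0.51, adjusted p = 0.0660), both driver genes of this leukaemia type, were not called.

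Macrophage and monocyte genes were higher in both shMed12 libraries. Of 24 tested genes 6 rose, 0 fell and 18 were not called, and 16 rose when adjusted over the list alone, with a median of 0.60 (camera adjusted p = 4.50e-10; adjusted p = 0.318 with an estimated correlation). Emr1, which encodes the macrophage antigen F4/80, went from 23.9 to 63.8 ± 5.55 FPKM (log2 fold change 1.38), and the chemokine Ccl6 from 9.60 to 21.5 ± 0.738 FPKM (1.08). Lysosome and autophagy genes had a median of 0.29, with 3 of 25 called, among them the cathepsins Ctsl (1.39) and Ctsb (0.56), and 7 higher when adjusted over the list alone (camera adjusted p = 6.32e-07; adjusted p = 0.318 with an estimated correlation). Ctsb shares its listed locus with another gene. Of 11 interferon-stimulated genes 2 rose, Isg20 (0.94) and Irf9 (0.74), and 6 rose when adjusted over the list alone (median 0.39, camera adjusted p = 5.66e-04; adjusted p = 0.318 with an estimated correlation). In antigen presentation genes 0 of 9 were called and 3 rose when adjusted over the list alone (median 0.26, camera adjusted p = 0.0193; adjusted p = 0.417 with an estimated correlation), and the list call ended without genes of a shared locus.

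Neutrophil granule genes moved in both directions after Med12 knockdown. The primary granule proteases Ctsg (-1.14) and Elane (-1.12), made at the promyelocyte stage, fell, and Cd177, a surface protein of neutrophils, rose (1.34). Of 15 tested genes 4 fell, 1 rose and 10 were not called, with 4 and 2 when adjusted over the list alone, and the list was not called (median -0.01, camera adjusted p = 0.809). The median of this list was -0.61 with shMed12.401 and 0.58 with shMed12.5755. Cholesterol synthesis genes were called as a list (median 0.34, camera adjusted p = 0.00182; adjusted p = 0.716 with an estimated correlation) with 0 of 25 genes called, and 0 when adjusted over the list alone. Their median was 0.74 with shMed12.401 and -0.050 with shMed12.5755, so the list call rested on 1 library. G2/M genes had 0 of 32 called, and 0 when adjusted over the list alone, at a median of 0.05 (camera adjusted p = 0.0484; adjusted p = 0.716 with an estimated correlation), and the call ended without shMed12.401, at a median of 0.00199, and in 7 other settings. E2f2, a cell cycle transcription factor, rose (1.00) as the 1 called gene of 36 in the G1/S list, which was not called (camera adjusted p = 0.211), with 1 gene also when adjusted over the list alone. The integrin chain Itgb3, the 1 tested megakaryocyte marker, rose (1.16).

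Besides the granule and G1/S lists, those not called after Med12 knockdown had camera adjusted p from 0.0608 (immediate early genes) to 0.809 (TGF-beta target genes), and also covered p53 targets (0.182), glycolysis and hypoxia genes (0.0692), stem cell and early progenitor genes (0.718) and both Mediator lists (0.387 and 0.544). In these, 0 genes were called other than Kit in the stem cell list, and when adjusted over the list alone 3 p53 targets and 2 stem cell genes were lower and 0 genes passed in the rest. For TGF-beta targets the median (-0.04) and the test (up) differed in sign. The count of 484 fell to 45 without shMed23.678 and to 46 without shMed23.4061, and was 851 without shMed12.401. Median-of-ratios scaling gave 415 calls with 242 higher and 173 lower, and quantile normalization 538 with 280 higher and 258 lower, so the split between rises and falls depends on the scaling.

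After Med23 knockdown Lsp1 and Wfdc17 rose and Myc, Kit and Elane fell. Lsp1 rose from 5.54 to 34.4 and 27.5 FPKM and Wfdc17, a small secreted protein of myeloid cells, from 33.3 to 104 ± 3.17 FPKM (SD, n = 2). Myc fell from 87.0 to 42.8 ± 0.543 FPKM and Kit from 43.2 to 23.5 ± 2.23 FPKM. Elane, the neutrophil elastase gene, fell from 2433 to 810 ± 218 FPKM. In total 68 of 8285 genes were called, of which 43 rose and 25 fell. The order of the 2 counts depended on the fit: shMed23 had more calls than shMed12 in a fit of the compared groups alone (555 against 45) and without shMed12.5755 (552 against 531).

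Among called genes, with the same symbols aside, the 10 largest rises after Med23 knockdown were in Lsp1 (log2 fold change 2.28, SE 0.14, adjusted p = 0.0259), Wfdc17 (1.62), Alox5 (1.28), Exoc1 (1.26), Il18rap (1.22), Ndrg1 (1.22), Apobr (1.09), Evi2a (1.08), Slfn2 (1.07) and Hmox1 (1.05). Alox5 makes leukotrienes and Hmox1 degrades haem, and both are expressed in macrophages. Evi2a shares its listed locus with another gene. The 10 largest falls among them were in Matk (-1.61, SE 0.15, adjusted p = 0.0373), Elane (-1.61, SE 0.23, adjusted p = 0.0496), Med23 itself, Fam195a (-1.28), Fgl2 (-1.18), Phgdh (-1.12), Ydjc (-1.02), Myc (-1.01), Retsat (from 8.19 to 3.59 ± 0.173 FPKM) and Bzw2 (-0.98). Some genes that were not called had larger changes, such as S100a6 (2.40) and Camp (-1.70), both named after their values were seen. Matk, a kinase that acts on SRC family kinases, went from 11.5 to 3.10 ± 0.630 FPKM. Of the fixed genes, Itgam rose from 176 to 351 ± 10.3 FPKM (0.99, SE 0.10, adjusted p = 0.0419). Hoxa9 (0.27, adjusted p = 0.433), Meis1 (0.50, adjusted p = 0.0927), Myb (-0.21, adjusted p = 0.395), Cdk6 (-0.34, adjusted p = 0.326), Bcl2 (0.07, adjusted p = 0.739) and Brd4 (-0.07, adjusted p = 0.767) were not called.

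The list of MYC targets had a median of -0.48 in shMed23 cells (camera adjusted p = 2.28e-12; adjusted p = 0.538 with an estimated correlation; fry adjusted p = 0.185). Of 42 genes 2 fell, Bzw2 and the ribosome assembly factor Ppan (-0.70), 0 rose and 40 were not called, and 34 fell when adjusted over the list alone. Cytosolic ribosomal proteins had a median of -0.25 with 0 of 28 called, and 0 when adjusted over the list alone (camera adjusted p = 6.55e-05; adjusted p = 0.413 with an estimated correlation). Phgdh was the 1 called gene of 24 in the ATF4 list, in which 7 were lower and 1 higher when adjusted over the list alone (median -0.39, camera adjusted p = 4.50e-04; adjusted p = 0.363 with an estimated correlation). Of 14 genes sensitive to BET inhibitors, Kit (-0.85) and Myc fell and 12 were not called, with 4 lower and 1 higher when adjusted over the list alone, and this list was not called (camera adjusted p = 0.756). G2/M genes had a median of -0.16 with 0 of 32 called, and 0 when adjusted over the list alone (camera adjusted p = 0.00165; adjusted p = 0.785 with an estimated correlation), a call that ended without shMed23.678, at -0.13.

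Macrophage and monocyte genes had a median of 0.52 in shMed23 cells (camera adjusted p = 1.48e-10; adjusted p = 0.357 with an estimated correlation). Of 24 genes 3 rose (Emr1 at 1.00, Ccl6 at 0.99 and Itgam), 0 fell and 21 were not called, and 13 rose and 1 fell when adjusted over the list alone. Lysosome and autophagy genes had 0 of 25 called and 8 higher when adjusted over the list alone (median 0.22, camera adjusted p = 4.16e-08; adjusted p = 0.357 with an estimated correlation). Interferon-stimulated genes had 0 of 11 called and 4 higher when adjusted over the list alone (median 0.31, camera adjusted p = 0.00182; adjusted p = 0.357 with an estimated correlation). MLL-AF9 and HOXA9 targets had 0 of 13 called and 3 higher when adjusted over the list alone (median 0.27, camera adjusted p = 4.50e-04; adjusted p = 0.357 with an estimated correlation). Antigen presentation genes had 0 of 9 called, and 0 when adjusted over the list alone (median 0.22, camera adjusted p = 0.00478; adjusted p = 0.357 with an estimated correlation). Immediate early genes had 0 of 16 called and 1 higher when adjusted over the list alone (median 0.26, camera adjusted p = 0.00956; adjusted p = 0.410 with an estimated correlation), a call that ended without shMed23.678, at 0.25.

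Neutrophil granule genes had a median of -0.59 in shMed23 cells, with Elane the 1 called gene of 15 and 3 lower when adjusted over the list alone (camera adjusted p = 0.0374; adjusted p = 0.802 with an estimated correlation). Without shMed23.678 this list was not called, at -0.47, and neither was it without a filter or with the transcript length correction. Of 3 tested mast cell and basophil markers, Mcpt8, a basophil protease, fell (-0.82), and Kit was the 1 called gene of 10 in the stem cell list, which was not called (camera adjusted p = 0.868; 1 higher and 1 lower when adjusted over the list alone). Other lists not called had camera adjusted p from 0.0870 (cholesterol synthesis) to 0.911 (kinase module of Mediator), and also covered glycolysis and hypoxia genes (0.116), heat shock genes (0.157), TGF-beta targets (0.207), G1/S genes (0.311), other Mediator subunits (0.749) and p53 targets (0.756). In these, 0 genes were called, and when adjusted over the list alone 3 heat shock genes were lower and 1 p53 target was higher. The median (-0.06) and the test (up) of p53 targets differed in sign. The count of 68 fell to 1 without shMed23.678 and to 1 without shMed23.4061, and was 553 without shMed12.401 and 552 without shMed12.5755. Median-of-ratios scaling gave 69 calls with 54 higher and 15 lower, against 43 and 25.

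**Figure D2:**
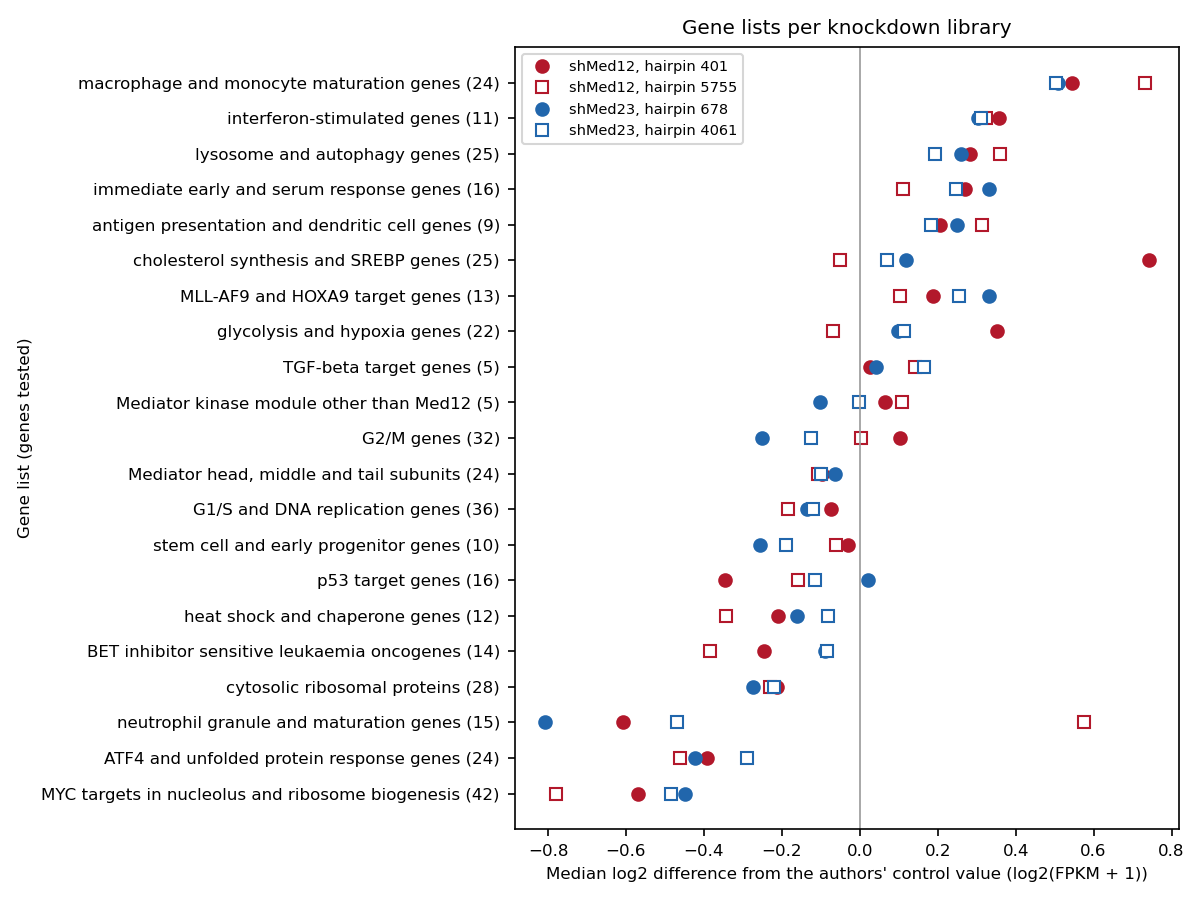
Median difference from the authors' control value, on the log2(FPKM + 1) scale, of each of 21 gene lists in each knockdown library; red marks are shMed12 libraries, blue marks shMed23 libraries, and the number of tested genes is in brackets. The MYC target list lay between -0.78 and -0.45 and the macrophage list between 0.50 and 0.73 in all 4 libraries, while the neutrophil granule list lay at 0.58 with shMed12.5755 and below 0 with the other hairpins.

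Genes called after Med12 knockdown were also called after Med23 knockdown in part. Of genes that rose, 36 were shared between the 206 and 43 called, and of genes that fell, 21 were shared between the 278 and 25 called. Independent lists of those sizes would share 1.07 and 0.839 genes. In simulated unchanged groups against 1 control value, lists of those sizes taken by rank of p shared a mean of 25.8 genes that rose (18 to 32) and 18.01 that fell (11 to 23). The overlap of falls lay inside that range and that of rises above it. The simulation drew each gene independently, so its ranges may be too narrow, and part or all of the excess may come from the shared control. Of all called genes, 0 were called in opposite directions, which the shared control value alone makes unlikely. No simulated count was set beside this. The shared rises with the largest smaller change were in Lsp1, Wfdc17, Il18rap, Alox5 (1.16 and 1.28 in shMed12 and shMed23) and Apobr (1.17 and 1.09). The shared falls were led by Fam195a (-1.24 and -1.28), Phgdh (-1.14 and -1.12), Elane (-1.12 and -1.61), Fgl2 (-1.08 and -1.18) and Ydjc (-1.06 and -1.02).

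Across 8285 genes, which are not independent replicates, the log2 fold changes of the 2 knockdowns had a Pearson r of 0.790 and a Spearman rho of 0.765. Simulated unchanged groups that shared a control value gave a mean r of 0.665 and rho of 0.641. The covariance was 0.0759, against 0.0128 in the simulation, a difference of 0.0631. Genes with the same sign made up 79.7%, against 73.2%. The simulation drew each gene independently and gave the control value the spread of 1 library, so its values may understate what a shared control gives. The control could not be split because the table gives 1 value, so part or all of the excess may come from the shared control. Without shMed12.401 r was 0.661. Set against the control value 1 at a time, the 2 shMed12 hairpins had an r of 0.765 and the 2 shMed23 hairpins one of 0.869, against 0.499 in simulation. Hairpins of different targets gave 0.777 (shMed12.401 and shMed23.678), 0.823 (shMed12.401 and shMed23.4061), 0.735 (shMed12.5755 and shMed23.4061) and 0.562 (shMed12.5755 and shMed23.678), so r was not higher within a target than between targets for shMed12.401. Between the shMed12 hairpins 41 genes differed over 2-fold, and between the shMed23 hairpins 20.

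**Figure D3:**
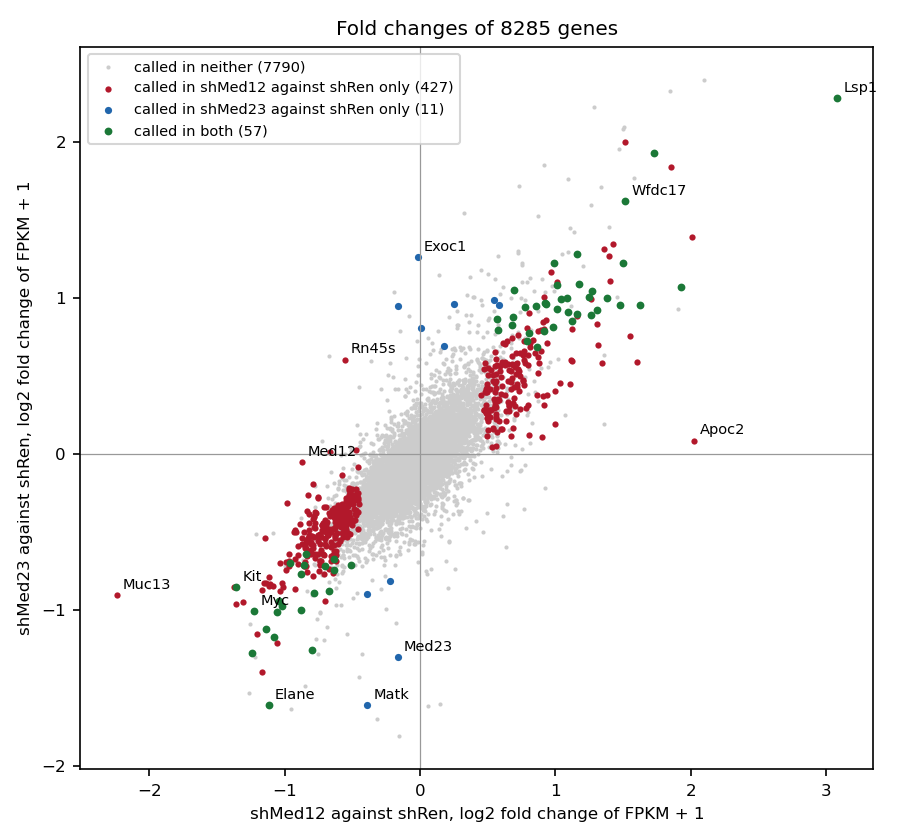
Log2 fold changes of FPKM + 1 against the authors' control value for 8285 genes, with shMed12 on the horizontal and shMed23 on the vertical axis; each point is a gene and colours mark called genes. The 57 genes called in both comparisons lie in the lower left and upper right, and Apoc2, Exoc1, Rn45s and Med23 stand apart from the diagonal.

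When shMed12 and shMed23 libraries were compared directly, 4 of 8285 genes were called by limma, against 1192 at an unadjusted p under 0.05. Apoc2 was higher in shMed12 libraries, at 43.7 ± 1.60 against 10.8 ± 2.50 FPKM (SD, n = 2 each; log2 difference 1.94, SE 0.15, adjusted p = 0.0315). Exoc1, a subunit of the exocyst complex of vesicle transport, was higher in shMed23 libraries, at 63.9 ± 6.21 against 25.7 ± 0.00665 FPKM (-1.28, SE 0.09, adjusted p = 0.0315). Med23 was higher in shMed12 libraries (1.14, SE 0.09, adjusted p = 0.0315). Rn45s, the ribosomal RNA precursor, was higher in shMed23 libraries, at 133 ± 5.34 against 59.2 ± 4.08 FPKM (-1.16, SE 0.09, adjusted p = 0.0315). The difference in Med12 itself was not called (-0.82, SE 0.08, adjusted p = 0.0530), nor that in Matk (1.22, SE 0.13, adjusted p = 0.0530) or Muc13 (-1.33, SE 0.19, adjusted p = 0.139). The count was 15 without shMed12.401, 1 without shMed12.5755 and 0 without shMed23.678.

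As lists, 8 differed between the 2 knockdowns by camera, with 0 called genes in each. MYC targets were lower in shMed12 than in shMed23 libraries (median difference -0.20, camera adjusted p = 5.91e-12; adjusted p = 0.631 with an estimated correlation), with 0 of 42 also when adjusted over the list alone. Against the control value their medians were -0.57 with shMed12.401, -0.78 with shMed12.5755, -0.45 with shMed23.678 and -0.48 with shMed23.4061. Hairpin shMed12.401 thus lay closer to the shMed23 hairpins than shMed12.5755 did. G2/M genes were higher in shMed12 libraries, with 17 of 32 when adjusted over the list alone (0.27, camera adjusted p = 1.35e-12; adjusted p = 0.631 with an estimated correlation). Genes sensitive to BET inhibitors were lower in shMed12 libraries, with 2 of 14 when adjusted over the list alone (-0.22, camera adjusted p = 2.07e-05; adjusted p = 0.631 with an estimated correlation). ATF4 genes (-0.12, camera adjusted p = 0.00319), p53 targets (-0.16, camera adjusted p = 0.00462) and heat shock genes (-0.16, camera adjusted p = 0.0202) were lower in shMed12 libraries, each at adjusted p = 0.631 with an estimated correlation and with 0 genes when adjusted over the list alone. Neutrophil granule genes (0.61, camera adjusted p = 0.00462; adjusted p = 0.671 with an estimated correlation) and cholesterol synthesis genes (0.23, camera adjusted p = 0.0202; adjusted p = 0.787 with an estimated correlation) were higher in shMed12 libraries, with 0 genes when adjusted over the list alone. The granule call ended without shMed12.5755 (median 0.26) and without shMed23.678 (0.34), and the cholesterol list lay at -0.092 without shMed12.401 and was not called without shMed23.4061. The calls of p53 targets without shMed12.401 (-0.07), of ATF4 genes without shMed23.4061 (-0.16) and of heat shock genes without shMed12.5755 (-0.11) or shMed23.4061 (-0.09) also ended. The other 13 lists were not called, with camera adjusted p from 0.102 to 0.996, and those of macrophage genes (0.417) and cytosolic ribosomal proteins (0.753) were among them. When adjusted over the list alone, 1 G1/S gene, 1 interferon-stimulated gene and 1 stem cell gene were higher and 2 stem cell genes lower in shMed12 libraries. In the G1/S and stem cell lists the mean (0.02 in both) differed in sign from the median and the test.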

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

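The tests of explanations in this part were chosen after the results were seen. The difference between the 2 knockdown effects was tested directly and was past the threshold for Apoc2 (log2 difference 1.94, higher in both shMed12 libraries), Med23 (1.14), Exoc1 (-1.28, higher in both shMed23 libraries) and Rn45s (-1.16). Med23 is the gene targeted in shMed23 cells. Bcl2 lay below the control value in both shMed12 libraries and above it in both shMed23 libraries, with a difference of -0.22 that was not past the threshold (adjusted p = 0.355). It shares its listed locus with another gene, and shMed23.4061 was level with the control value (10.098 against 10.094 FPKM), so the opposite sign rests on shMed23.678 alone. As lists, MYC targets (median difference -0.20), genes sensitive to BET inhibitors (-0.22), p53 targets (-0.16), ATF4 genes (-0.12) and heat shock genes (-0.16) were lower in shMed12 than in shMed23 libraries. G2/M genes (0.27), neutrophil granule genes (0.61) and cholesterol synthesis genes (0.23) were higher. With an estimated correlation 0 of these lists passed.

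Rn45s was higher in both shMed23 libraries (129 and 137 FPKM) than in both shMed12 libraries (56.3 and 62.1 FPKM), with the control value between them at 87.4 FPKM. Lars2 (log2 difference -1.11, adjusted p = 0.0530) and Mir6236 (-1.23, adjusted p = 0.0955), picked after their values were seen because mouse loci of these names hold sequence like ribosomal RNA, differed alike without being called in this comparison. Against the control value, limma called the fall of Rn45s in shMed12 cells (log2 fold change -0.56, adjusted p = 0.0465). It also called the rise of Lars2 in shMed23 cells (0.95, adjusted p = 0.0470). Rn45s in shMed23 cells (0.60), Lars2 in shMed12 cells (-0.16) and Mir6236 in shMed12 and shMed23 cells (-0.19 and 1.03) were not called. Weaker poly(A) selection in the shMed23 libraries would raise all RNAs without a poly(A) tail there by about as much, and is argued against as the whole cause. The 14 others tested had a median difference of 0.18 (SD 0.33), in the other direction. Small RNA genes listed at 0 in a library were left out of the test, so any such RNAs among them were not covered. Of these, 10 are histone RNAs, whose level follows the cell cycle. The 4 others had a median of -0.068 (SD 0.35), with Rpph1 (-0.26) and Rn4.5s (-0.14) higher in shMed23 libraries, Rnu73b at 0.0062 and Snora52 at 0.53. A small difference in selection stays open. Ribosomal RNA carried over in different amounts stays open: between the hairpins of 1 target the 3 features did not follow each other closely, with ranges of up to 0.49 (log2), but those gaps are small beside the difference between targets. An effect of the knockdowns on ribosomal RNA synthesis was not tested and stays open too.

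Neutrophil granule genes differed between the hairpins of 1 target. Ngp was at 156 FPKM with shMed12.401 and 606 with shMed12.5755, and at 88.6 with shMed23.678 and 192 with shMed23.4061, and 12 and 15 of the 15 listed genes were lower with shMed12.401 than shMed12.5755 and with shMed23.678 than shMed23.4061. The 5 granule genes over 2-fold apart between the shMed12 hairpins had a median of 47.5 FPKM, above the 20.1 FPKM of all genes. As a set they were thus not weakly expressed by FPKM. Counting noise itself stays open, since FPKM values carry no read counts. The difference of shMed12.401 from shMed12.5755 correlated with that of shMed23.678 from shMed23.4061 across 8226 other genes (r = 0.391, against at most 0.0371 in 1000 shuffles of genes). The shuffles break the correlation between genes, so they do not show how large an r correlated genes could give. Only the 15 granule genes and small RNA symbols were left out, so genes that vary with the granule genes may remain. A difference between cultures or preparations not tied to 1 hairpin would give such an r, and may account for part of the granule differences. Hairpin effects outside the target, or unlabelled batches of culture or library preparation, stay open, since genes are not independent and each hairpin has 1 library.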

How the results depend on the processing

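Counts of calls moved with the settings. All 8285 genes of the main test passed the mean FPKM filter, so the setting without a filter only added small RNA genes listed at 0. Of the genes called for shMed12 against shRen, 483 of 484 kept their direction with quantile normalization, and all called genes that could be tested kept it in the other settings and comparisons. The depth of the libraries is unknown, so its limit could not be assessed. No paired analysis was possible because replicate numbers occur in the labels of shRen alone. Use of 1 shRen library per comparison and leaving out a shRen library were not run, since the table gives 1 control value, and count-based tests were not run, since it holds no counts. The settings of control weight, shared loci, symbols and transcript length were chosen after seeing the data. The cause of a change was otherwise not tested. In comparisons with shRen, a left-out library or a fit of the compared groups leaves 1 pair of hairpins to estimate the spread. The log2 difference between hairpins had an SD of 0.23 across genes for shMed12 and 0.17 for shMed23. Counts against shRen were lower where the shMed12 pair alone was left and higher where the shMed23 pair alone was left.

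For shMed12 against shRen (484 calls) the count was 169 without a filter, 45 in a fit of the compared groups alone, 27 with treat at a fold of 1.2, 1450 with the control weighted as 2 libraries, and 45 to 851 when 1 library was left out. For shMed23 against shRen (68 calls) it was 110 with a pseudocount of 5, 0 without a filter, 174 with quantile normalization, 555 in a fit of the compared groups alone, 34 without the variance trend, 108 with robust eBayes, 2 with treat, 999 with the control weighted as 2, 104 without shared loci, 107 without Mir, Snor, Rnu, Gm and Rik symbols, 0 with the transcript length correction, and 1 to 553 when 1 library was left out. At an unadjusted p under 0.05 the main limma fit had 1955 genes there. For shMed12 against shMed23 (4 calls) it was 8 with a pseudocount of 5, 9 without a filter, 10 with quantile normalization, 9 with robust eBayes, 0 with treat, 9 without shared loci, 9 without those symbols, 0 with the length correction, and 0 to 15 when 1 library was left out. The correlation of fold changes (0.790) was 0.671 without a filter and 0.661 to 0.829 when 1 library was left out.

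The fall of Med12 in shMed12 cells kept its size but lost its call in a fit of the compared groups (-0.88) and with treat (-0.88), and ranged from -0.88 to -0.87 when 1 library was left out. That of Med23 in shMed23 cells lost its call without a filter (-1.30), with treat (-1.30) and with the length correction (-1.33), and ranged from -1.35 to -1.26. With an estimated correlation 0 lists passed in each comparison, against 12, 11 and 8. When 1 library was left out these were 9 to 14, 8 to 13 and 5 to 10. The sign turned for values of genes that were not called: in shMed12 cells Hoxa9 (-0.083 without shMed12.401, up to 0.40 when 1 library was left out) and Brd4 (-0.0094 with the length correction, -0.069 without shMed12.5755, up to 0.12), and in shMed23 cells Med12 (0.0087 with median-of-ratios scaling, 0.013 with quantile normalization). The cholesterol list turned without shMed12.401, with medians from -0.050 to 0.74 in shMed12 against shRen and from -0.092 to 0.59 in shMed12 against shMed23 when 1 library was left out. Over other named genes and settings 1219 values kept direction and side of the threshold, 273 lost the call and 6 gained it, and over called lists 530 kept it and 57 lost it. The settings without the variance trend, with robust eBayes and with treat do not enter camera. The 31 list calls kept in each of these therefore only repeat the main result. Median-of-ratios scaling moves genes almost alike, so its 31 kept list calls add little.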

Other observations

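The families, the genes named and the tests of explanations in this part were chosen after the values were seen. The limma test of each gene, the MYC target and macrophage lists and median-of-ratios scaling had been fixed before. The 12 families in the next sentences were picked by gene symbol after their values were seen, so no p-value is given for them, and medians are log2 fold changes in shMed12 and shMed23 cells. Genes that host small nucleolar RNAs (Snhg genes and Gas5) had medians of -0.59 and -0.61 with 3 and 0 of 10 called. Gas5 fell in shMed12 cells (log2 fold change -0.74, adjusted p = 0.0304) and was at -0.75 in shMed23 cells (adjusted p = 0.0559). The 76 mitochondrial ribosomal proteins had medians of -0.28 and -0.20 with 7 and 0 called. The 15 subunits of RNA polymerases I and III had medians of -0.35 and -0.27 with 5 and 0 called, and the 19 aminoacyl-tRNA synthetases -0.33 and -0.22 with 2 and 0. The 41 genes with an Nduf symbol had -0.23 and -0.17 with 1 and 0. Most encode subunits of mitochondrial complex I, and those with an Ndufaf symbol encode its assembly factors. The 7 chaperonin subunits had -0.32 and -0.12 with 0 and 0. The 38 genes with a Psm symbol, most of them proteasome subunits, had -0.11 and -0.0045 with 1 and 0. Their second median turned to 0.060 with median-of-ratios scaling and 0.016 with quantile normalization. Higher medians were those of 17 genes with an Atp6v or Atp6ap symbol (0.18 and 0.19 with 0 and 0 called). Most of them encode subunits of the vacuolar ATPase, which acidifies lysosomes. Medians were also higher for 8 S100 proteins (0.55 and 0.44 with 0 and 0). The 12 genes grouped as C-type lectin and Lilr receptors had 0.58 and 0.65 with 3 and 0, and 4 schlafen genes 0.50 and 0.33 with 1 and 1. Directions other than that of the Psm genes were the same under both scalings.

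Among 5 listed chemokine genes the medians were 1.08 and 1.02 with Ccl6 the 1 called gene in each comparison. Ccl3 was at 91.6 and 63.7 FPKM in shMed12 libraries and 156 and 84.6 FPKM in shMed23 libraries against a control value of 26.4 FPKM, and was not called (adjusted p = 0.0670 and 0.0609). S100a6 was at 42.8 and 18.8 FPKM and 42.6 and 29.1 FPKM against 5.89 FPKM, and was not called either (adjusted p = 0.0503 and 0.0623). The next genes on chromosome 5, Tmem165, Clock and Exoc1 (76612904 to 76999323, mm9), were all higher in both shMed23 than in both shMed12 libraries, by 0.65, 0.80 and 1.28 (log2), of which the last was called. Against the control value, Clock (0.81, adjusted p = 0.0462) and Exoc1 (1.26) rose in shMed23 cells and were about level in shMed12 cells (0.0057 and -0.016). Tmem165 was called in neither comparison, at 0.18 in shMed23 and -0.47 in shMed12 cells, so its difference came mainly from the shMed12 libraries. The flanking listed genes Srd5a3 and Cep135 differed by 0.05 and 0.05 in the same direction. Rps27 was at 49.7 and 94.8 FPKM with hairpins shMed12.401 and shMed23.678 and at 5.74 and 3.61 FPKM with hairpins shMed12.5755 and shMed23.4061, against a control value of 5.17 FPKM.

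In all 4 knockdown libraries the MYC target list lay below the control value and the macrophage list above it. A trend with transcript length is argued against as the whole cause: after correction both lists still passed camera at the preset correlation in both comparisons, and the smallest of their 4 medians was 0.49 in size. The authors' scaling between libraries is argued against as the whole cause by the medians alone, with 0.41 as the smallest in size after median-of-ratios scaling. Camera sets a list against all other genes, which such scaling moves almost alike, so a passed camera test could not count here. A deviation of the single control value cannot be told apart from an effect of both knockdowns, since all comparisons with shRen use that value. Such a deviation gives no difference between the knockdowns, and the MYC target list differed there by -0.20 (camera adjusted p = 5.91e-12 at the preset correlation, not passed with an estimated correlation). That is smaller than its median of -0.48 in shMed23 cells, so the part common to both knockdowns is not decided by it. The size of the difference also depended on the hairpin, with shMed12.401 at -0.57 and shMed12.5755 at -0.78 against the control value. The hypothesis that loss of either subunit lowers MYC targets and raises macrophage genes therefore stays open, and needs the separate shRen values.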
